A study of Mus musculus with 30 samples.

How the data were processed

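The submitters' processing notes name robust multi-array averaging (RMA) in Affymetrix Expression Console 1.4; other settings are not given in the sources used here. The deposited matrix holds log2 values, and these were used as deposited without further scaling. It has 72688 probe sets in 30 arrays, of which 65956 are transcript clusters and 6732 are controls, among them 1324 exon and 5222 intron controls. Values ran from 2.45 to 19.93. Values above 16 exceed what a 16-bit scanner can give, so the scale was stretched by a step not given in the sources used here; a difference of 1 unit is therefore not read as a doubling. All columns were used, and each array came from a separate animal according to the labels.

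Gene symbols came from the platform annotation: 30604 probe sets carried 1 symbol, 2146 several, and 33206 clusters none. Symbols were brought up to date through the gene identifier where this was possible (22815 probe sets, 827 symbols changed), and 7789 kept the symbol of the annotation. This gave 30142 symbols; for 355 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used. Genes with a log2 value of at least 5 in at least 3 arrays were tested, 24099 in all, of which 398 share identical values with another gene. Array signal does not fall to 0 without transcript: intron controls had array medians of 5.73 to 6.79, so the filter lies below the level of intron controls, and small differences of weakly expressed genes are compressed by background. Ren1 has no probe set with that symbol alone and is not analysed here. Gene positions were taken from a mouse gene table of assembly GRCm38.p6 and used only as distances from Lep.

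A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (residual df 22, prior df 3.16, median residual SD 0.20). Comparisons were ob/ob against wild type at each age, 24 against 4 weeks in each genotype, the change of the genotype difference from 4 to 24 weeks, and an F test of that difference over 4 ages. P values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. Positive differences are higher in ob/ob, or higher at 24 weeks for ageing.

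These 27 gene lists, the comparisons and the rule for naming genes were set before the data were examined: podocyte, glomerular endothelial, mesangial and smooth muscle, parietal epithelial, proximal tubule, distal nephron and collecting duct, macrophage and myeloid, lymphocyte, erythroid, adipocyte, basement membrane, fibrosis and interstitial matrix, complement, inflammatory cytokine and adhesion, interferon response, oxidative stress and NRF2 targets, lipid and sterol synthesis, fatty acid oxidation and PPAR targets, oxidative phosphorylation, glycolysis and hypoxia response, cell cycle, unfolded protein response, immediate early, kidney injury markers, renin-angiotensin and vasoactive, insulin, IGF and leptin signalling, and circadian clock. Some genes sit in more than 1 list. The erythroid list had 2 measured members and was not tested. The other 26 were tested in 7 comparisons, 182 tests adjusted together, with limma's camera at a preset correlation of 0.01, then with an estimated correlation, and with fry. Members were also adjusted over the list alone.

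Genes named in the text were taken by rule: the 10 largest rises and 10 largest falls past the threshold in each genotype and ageing comparison, leaving out predicted, unnamed and olfactory or similar large-family genes, the 10 smallest p of each interaction test, up to 4 members of each list per comparison with the largest changes past the threshold, and Lep, Lepr, Nphs1, Wt1, Col4a1, Col4a3, Havcr1 and Slc34a1. The text names fewer than the rule allows. Group means of list signals per array were compared by two-sided exact permutation tests.

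In a simulation with the same numbers of arrays per group, 50 genes were given a true difference of each size. Noise was drawn independently for each gene and array, with 1 SD per gene, so correlated genes and arrays of poorer quality were absent. At 24 weeks 17, 46, 50 and 50 of 50 genes were recovered at 0.5, 1, 2 and 3 log2 units, with 10 false calls; at 4 weeks 16, 41, 48 and 50 were recovered, with 7 false calls. For the change from 4 to 24 weeks 6, 30, 43 and 50 were recovered. Recovery and false calls in the real arrays can differ from these: at 24 weeks a false regrouping of the real arrays called 6684 genes.

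Alternatives run were no filter, a filter at log2 6, only the arrays compared, cyclic loess scaling, array quality weights, empirical Bayes with trend and robust settings, the mean of a gene's probe sets, all probe sets, an absolute difference of at least 1, the proximal tubule list mean as covariate, replicate number as block, and each array left out in turn, which was extended to the called lists after the data had been seen. Overlaps were also taken from the top 500 genes by p, cell type lists as medians, and the Lep neighbourhood at 10 and 40 Mb. Tables were read with the data.table package, version 1.17.8, and figures drawn with matplotlib 3.10.9 and pandas 2.3.3.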

Results

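Glomeruli, the filtering units of the kidney, were isolated by sieving from female BTBR wild-type mice and from female BTBR ob/ob mice, which lack functional leptin and become obese and diabetic. Mice were 4, 8, 16 and 24 weeks old. RNA of each animal was measured on its own mouse transcriptome array, which gave 30 arrays in 8 groups, with 3 animals per genotype at 4 weeks and 4 per genotype at 8, 16 and 24 weeks. Signals were deposited as log2 values, and 24099 genes were tested. The deposited values reached 19.93, and 1.32% of the values of tested genes lay above 16, the limit of a 16-bit scanner, so an unstated step had stretched the scale and differences are given in log2 units as deposited, without linear folds. Differences are ob/ob minus wild type unless stated, with their standard error after ±. The number of animals limits the precision: the median standard error of a genotype difference was 0.16 log2 units at 4 weeks and 0.14 at 24 weeks. Each standard error uses 1 residual SD per gene pooled over all 8 groups. It therefore follows the number of animals and not the spread of the groups compared, which can be wider.

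The correlation between any 2 arrays across genes, which are not independent replicates, lay between 0.966 and 0.996. Array quality was read from control probe sets: the separation of exon from intron controls is the chance that a randomly drawn exon control is brighter than a randomly drawn intron control. It was 0.778, 0.783 and 0.762 in ob/ob 24 week replicates 1, 2 and 4, and 0.826 to 0.886 in the 27 other arrays, including 0.861 in ob/ob 24 week replicate 3. The spread of gene deviations, as an interquartile range, was 0.391, 0.444 and 0.512 in those 3 arrays and 0.283 in replicate 3. At 24 weeks the separation averaged 0.796 ± 0.044 (SD, n = 4) in ob/ob and 0.864 ± 0.023 (SD, n = 4) in wild type (exact permutation p = 0.0571, two-sided), and Benjamini-Hochberg adjustment over 8 quality comparisons gave 0.229. Many of the results at 24 weeks, though not all, stand beside values without these 3 arrays or with the separation as a covariate, both settings chosen after the data had been seen.

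**Figure D1:**
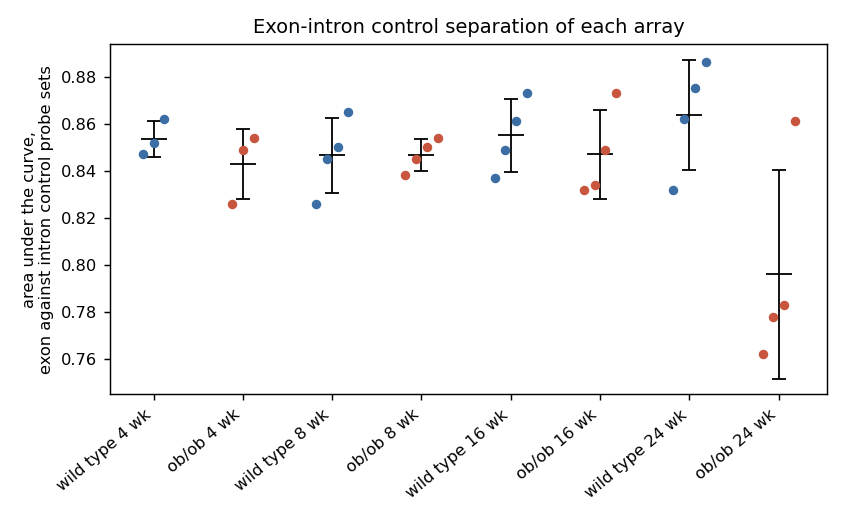
Separation of exon from intron control probe sets (y axis, 0.5 is no separation and 1 is full separation) in each of 30 arrays, by genotype and age in weeks; bars give the group mean and SD. The 3 lowest points, 0.762, 0.778 and 0.783, are all ob/ob animals of 24 weeks.

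Podocyte markers were the cell type group that stood apart most at 24 weeks. The mean of the 27 measured podocyte genes was 9.88 ± 1.05 log2 units (SD, n = 4) in ob/ob and 11.45 ± 0.09 (SD, n = 4) in wild type, a difference of -1.58 (exact permutation p = 0.0286). In the arrays of low separation the podocyte mean was 10.41 in replicate 1, 9.01 in replicate 4 and the lowest of all in replicate 2, and in ob/ob replicate 3 it was 11.09, against 11.32 to 11.52 in wild type. Glomerular endothelial markers differed by -1.10 and mesangial markers by -0.77 at 24 weeks (exact permutation p = 0.143 for each, n = 4 per genotype). Distal nephron and collecting duct markers were lower in ob/ob at 8 weeks, at 11.60 ± 0.16 against 12.52 ± 0.18 (SD, n = 4 each, exact permutation p = 0.0286). Proximal tubule markers, which measure carried-over tubule, had means near 15 to 16 in every group and differed by -0.16, -0.11, -0.19 and -0.43 at 4, 8, 16 and 24 weeks (smallest exact permutation p = 0.0571, n = 3 or 4 per genotype). Taken as medians of members, they differed by -0.82 at 24 weeks (exact permutation p = 0.0286, 0.343 after Benjamini-Hochberg adjustment). Within groups, over the 26 arrays outside ob/ob at 24 weeks, the proximal tubule mean rose with the separation (slope 11.7, SE 2.7). Carried beyond the range of those arrays, this slope gives a 24 week shift of -0.80 (95% interval -1.18 to -0.41). Tubule share and array quality can therefore not be told apart at that age. The parietal epithelial mean differed by -0.30 at 24 weeks (exact permutation p = 0.0286). Macrophage, lymphocyte and adipocyte means differed by -0.21 to 0.18 over the 4 ages. Their group means, 5.37 to 6.75, lay near the intron control medians of 5.73 to 6.79, where background compresses differences. The small range therefore does not show that these cells were unchanged. Over the 36 comparisons of 9 cell type lists and 4 ages, no difference passed Benjamini-Hochberg adjustment (smallest adjusted exact p = 0.343). With 3 against 3 animals the smallest possible two-sided exact p is 0.1, and with 4 against 4 it is 0.0286.

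**Figure D2:**
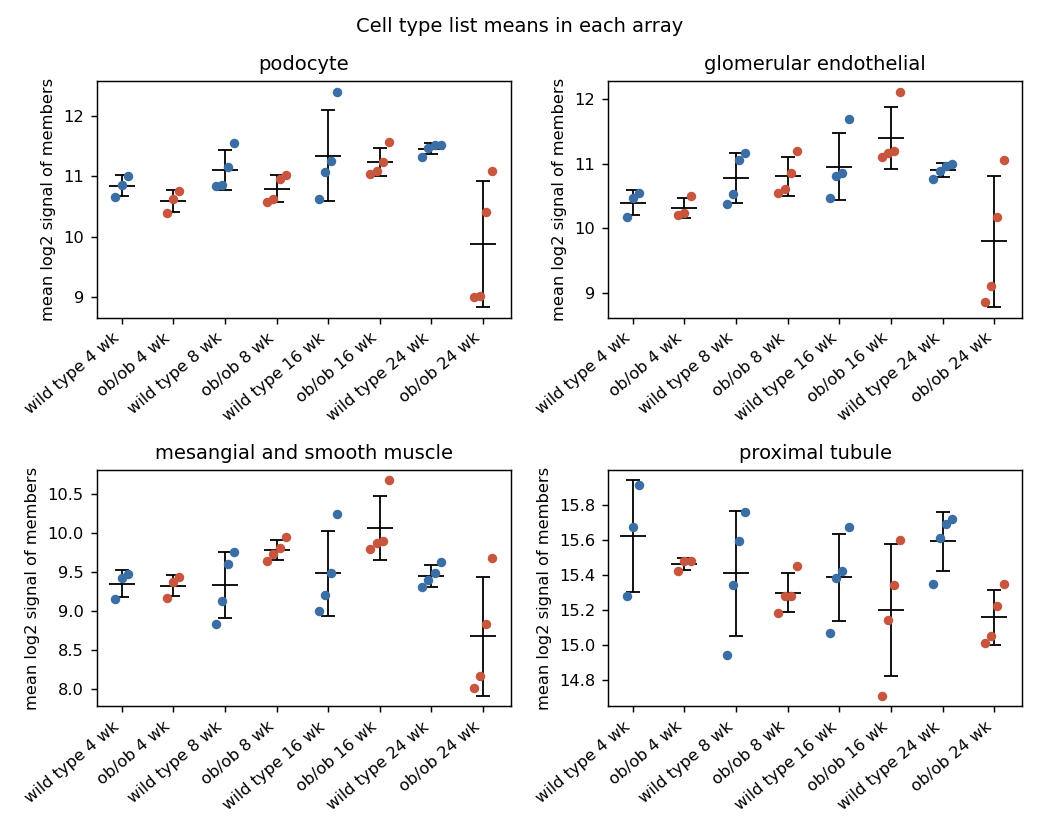
Mean log2 signal of the measured members of 4 cell type lists (y axis) in each array, by genotype and age; bars give the group mean and SD. In ob/ob at 24 weeks the podocyte mean averages 9.88 with an SD of 1.05, and in wild type at that age 11.45 with an SD of 0.09.

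The comparison at 4 weeks asks how ob/ob glomeruli differ from wild type in young animals. Akr1c18, which encodes a hydroxysteroid dehydrogenase that inactivates progesterone, differed by -2.33 ± 0.33 log2 units in ob/ob (adjusted p = 0.00512, n = 3 per genotype) and was the only gene past adjusted p 0.05 in limma. At unadjusted p under 0.05 there were 1082 genes. The podocyte genes Nphs1 (nephrin) and Wt1 differed by -0.13 and -0.19, and the basement membrane collagen Col4a1 by 0.10, none past the threshold. In limma's camera test with its preset correlation, 7 of 26 lists lay lower in ob/ob: lipid and sterol synthesis (median -0.47, adjusted p = 1.29e-14), interferon response (median -0.36, adjusted p = 6.04e-11), cell cycle (median -0.15), unfolded protein response (median -0.32), basement membrane (median -0.10), podocyte (median -0.17) and distal nephron (median -0.24). With an estimated correlation none of these calls held (adjusted p = 0.351 to 0.86 with an estimated correlation). Of the 18 lipid and sterol genes, 10 were lower when adjusted over the list alone, and all 18 interferon genes had a negative difference although no one of them passed by limma. The Akr1c18 call was lost with only the arrays compared (adjusted p = 0.525) and without ob/ob replicate 3, each of which left 0 genes. Without wild-type replicate 1, 6 genes passed. Leaving out 1 array, camera kept the lipid and interferon calls each time. It lost the calls for the unfolded protein response (highest adjusted p = 0.713), basement membrane (0.258) and distal nephron (0.492) lists without wild-type replicate 2. The cell cycle call was lost without wild-type replicate 1 (0.149) and the podocyte call without ob/ob replicate 1 (0.187), among others.

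At 8 weeks ob/ob samples carried more transcript of several transport and hormone genes. The sieved samples also held tubule. At this age the proximal tubule list averaged 15.30 in ob/ob and 15.41 in wild type, and the podocyte list 10.80 and 11.10. A change of a tubule gene may therefore lie in carried-over tubule, and in which cells the named genes changed was not tested at any age. Cyp24a1, which inactivates vitamin D, rose by 3.87 ± 0.83 log2 units (adjusted p = 0.0135, n = 4 per genotype), and Cyp27b1, which makes the active hormone, rose by 3.28 ± 0.80 (adjusted p = 0.0314). Slc5a10, a sugar transporter of the sodium-glucose family, rose by 2.81 ± 0.50, the fructose transporter Slc2a5 by 2.09 ± 0.42, the lipoprotein gene Apob by 2.66 ± 0.41 and angiotensinogen, Agt, by 2.14 ± 0.36. Kap, an androgen-regulated gene of the proximal tubule, fell by 4.60 ± 0.88 (adjusted p = 0.00608). Also lower were the organic anion transporter Slc22a19 (-3.40 ± 0.51), the Wnt antagonist Sfrp1 (-2.72 ± 0.55) and the calcium-sensing receptor, Casr (-2.33 ± 0.34). In all, 407 of 24099 genes passed, 154 higher and 253 lower.

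Of the fixed lists at 8 weeks, the distal nephron and collecting duct list fell most. Of its 20 members 6 were lower and 14 did not pass, while 14 were lower when adjusted over the list alone (median -0.83, camera adjusted p = 1.45e-14; adjusted p = 0.423 with an estimated correlation). Examples were the thiazide-sensitive transporter Slc12a3 (-1.75 ± 0.35), the potassium channel Kcnj1 (-1.60 ± 0.39) and parvalbumin, Pvalb (-1.44 ± 0.31). Lipid and sterol synthesis had 3 of 18 members lower, 9 when adjusted over the list alone: the desaturase Scd1 (-2.01 ± 0.40), the fatty acid synthase Fasn (-0.77 ± 0.20) and the sterol demethylase Cyp51 (-0.88 ± 0.21). The unfolded protein response had 3 of 18 lower, 9 when adjusted over the list alone, among them the stress transcription factor Xbp1 (-0.89 ± 0.22) and the chaperone partner Sdf2l1 (-1.20 ± 0.24). Insulin, IGF and leptin signalling had 3 of 20 lower, 6 over the list alone, among them the insulin receptor substrate Irs1 (-0.85 ± 0.19). Basement membrane had 3 of 18 higher, 5 over the list alone, with 1 lower over the list alone, among them nidogen, Nid1 (1.52 ± 0.38), and the collagen Col4a2 (1.27 ± 0.33). Mesangial and smooth muscle had 1 of 17 higher, the proteoglycan Cspg4 (0.71 ± 0.12), and a median of 0.37 (camera adjusted p = 2.72e-05; adjusted p = 0.635 with an estimated correlation). Fatty acid oxidation and PPAR targets had 1 of 21 higher, the lipid droplet gene Plin2 (1.03, adjusted p = 0.0489), 5 over the list alone, and a median of 0.62 (camera adjusted p = 3.98e-09; adjusted p = 0.5 with an estimated correlation). Camera also placed the inflammatory and cell cycle lists higher, and the podocyte, parietal and interferon lists lower, which made 5 lists higher and 7 lower of 26. None of the 12 calls held when the correlation was estimated (adjusted p = 0.423 to 0.891 with an estimated correlation). At the preset correlation, leaving out 1 array lost the podocyte (highest adjusted p = 0.353, without wild-type replicate 3), parietal (0.0756, without ob/ob replicate 3) and interferon calls (0.406, without wild-type replicate 4). The basement membrane (0.32) and inflammatory calls (0.289) were lost without wild-type replicate 2. Nphs1 differed by -0.04 ± 0.56 (adjusted p = 0.998) and Wt1 by -0.77 ± 0.45 (adjusted p = 0.552). The injury marker Havcr1 was lower in ob/ob (-1.57 ± 0.39, adjusted p = 0.038), and the keratin Krt8 higher (1.16 ± 0.25). The matrix genes Mmp2 (1.43 ± 0.35) and Col5a2 (-0.93 ± 0.15) passed in opposite directions.

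The count at 8 weeks was 237, 219, 234 and 166 genes without ob/ob replicates 1, 2, 3 and 4, and 254 and 173 without wild-type replicates 2 and 4. Cyclic loess scaling of the arrays turned 154 higher and 253 lower into 326 higher and 299 lower. Slc5a10, Apob, Agt, Slc2a5, Kap, Slc22a19, Sfrp1, Casr, Scd1, Slc12a3 and Sdf2l1 stayed past the threshold under all alternatives, while other genes named at 8 weeks lost the call under at least 1, with a highest adjusted p of 0.198 (Plin2). Those with an absolute difference below 1, such as Cspg4 and Xbp1, lose it by definition where a difference of at least 1 is required.

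**Figure D3:**
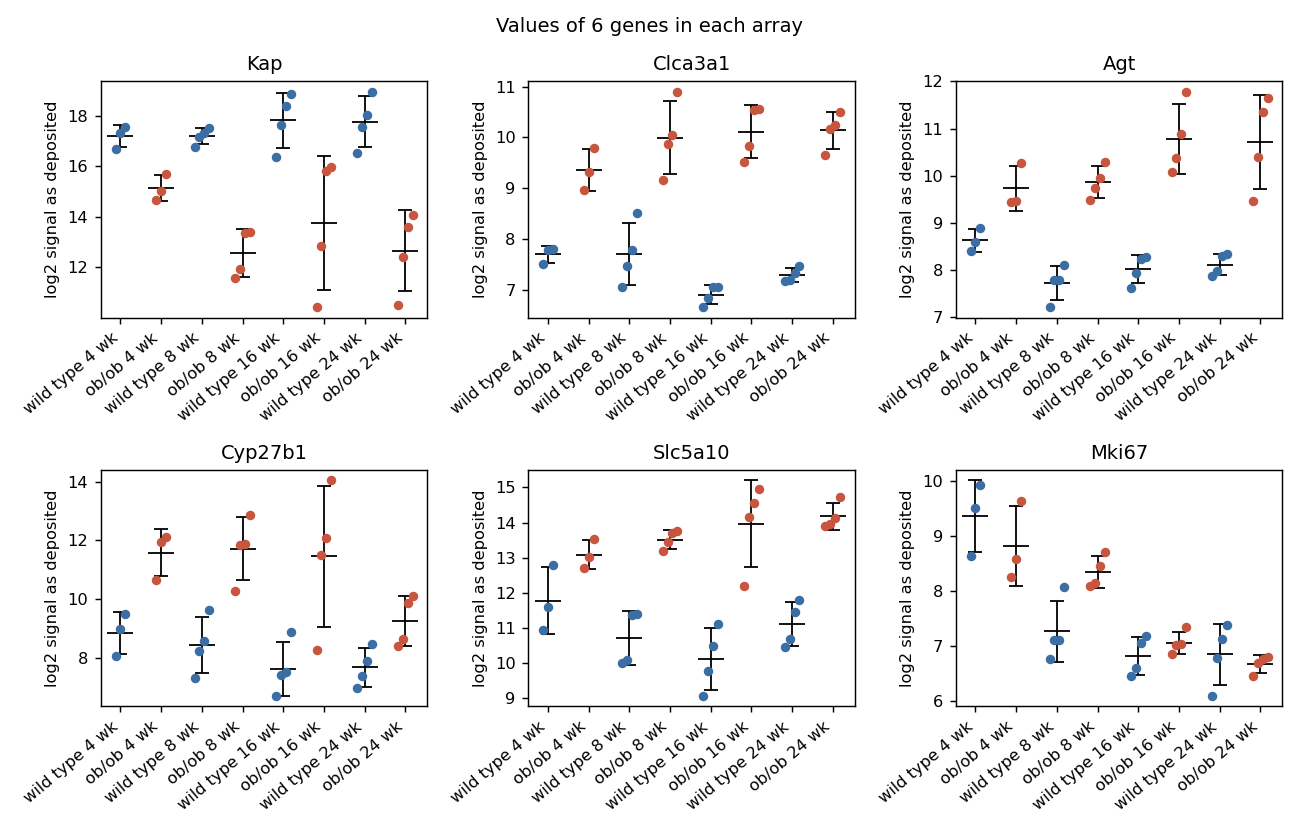
Log2 signal as deposited (y axis) of Kap, Clca3a1, Agt, Cyp27b1, Slc5a10 and Mki67 in each array, by genotype and age; bars give the group mean and SD. Kap averages 17.18 in wild type and 12.58 in ob/ob at 8 weeks, and Mki67 averages 9.35 in wild type at 4 weeks and 6.84 at 24 weeks.

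At 16 weeks the cell cycle inhibitor Cdkn1a showed the largest rise in ob/ob samples among the named genes, 3.96 ± 0.55 log2 units (adjusted p = 0.000232, n = 4 per genotype). Slc5a10 rose by 3.86, Cyp27b1 by 3.83 ± 0.80, the retinaldehyde dehydrogenase family gene Aldh1a7 by 3.28, the chloride channel regulator Clca3a1 by 3.21 ± 0.30 (adjusted p = 1.77e-06), Agt by 2.76 ± 0.36 and Apob by 2.69. Cyp27b1 varied widely in ob/ob at this age, with an SD of 2.40 and values of 8.26 to 14.04. In wild type its SD was 0.91 and its values 6.72 to 8.89, so the genotypes overlapped. Lower were Kap (-4.05 ± 0.88, adjusted p = 0.0117), the histidine decarboxylase Hdc (-3.87 ± 0.80), Slc22a19 (-3.54 ± 0.51) and albumin, Alb (-3.24 ± 0.86). In all, 542 genes passed, 220 higher and 322 lower.

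Fatty acid oxidation and PPAR targets had 5 of 21 members higher at 16 weeks and 16 not past the threshold, and 12 were higher when adjusted over the list alone (median 0.68, camera adjusted p = 4.04e-09; adjusted p = 0.5 with an estimated correlation). Examples were the lipoprotein lipase inhibitor Angptl4 (2.92 ± 0.58), the fatty acid hydroxylase Cyp4a14 (2.17 ± 0.55), the pantetheinase Vnn1 (1.95) and the thioesterase Acot1 (1.69). Lipid and sterol synthesis had 9 of 18 lower, 10 over the list alone (median -0.50, camera adjusted p = 3.9e-12; adjusted p = 0.351 with an estimated correlation), with Scd1 (-2.24 ± 0.40), the sterol sensor partner Insig1 (-1.71 ± 0.27) and Cyp51 (-1.57 ± 0.21). Kidney injury markers had 4 of 13 higher, 6 higher and 1 lower over the list alone, led by Cdkn1a (camera adjusted p = 1.32e-06; adjusted p = 0.351 with an estimated correlation), while Havcr1 differed by -1.20 ± 0.39 (adjusted p = 0.127). The proximal tubule list had 2 of 24 higher and 5 lower, 4 and 7 over the list alone, with the endocytic receptors Lrp2 (-0.97 ± 0.18) and Cubn (-1.08 ± 0.20) among the lower, and camera did not call it (adjusted p = 0.158). The distal nephron list had 6 of 20 lower, also 6 over the list alone, such as uromodulin, Umod (-1.12 ± 0.20), and the transporter Slc12a1 (-1.35 ± 0.34). Glycolysis and hypoxia response had 5 of 22 higher, 5 higher and 2 lower over the list alone, with adrenomedullin, Adm (2.45), and the pyruvate dehydrogenase kinase Pdk1 (0.73), and camera did not call it (adjusted p = 0.145). The fibrosis and matrix list had 3 of 28 higher and 1 lower, 7 and 2 over the list alone: the matricellular genes Ccn2 (2.47 ± 0.56) and Ccn1 (1.77 ± 0.39) were higher and the collagen Col5a2 (-1.06 ± 0.15) lower. Immediate early genes had 3 of 19 higher, 6 over the list alone, among them Fos (0.71 ± 0.17). Insulin, IGF and leptin signalling had 5 of 20 lower, 2 higher and 7 lower over the list alone, with the growth factor Igf1 at -0.85 ± 0.16. Of the renin-angiotensin and vasoactive list, Agt was higher and the converting enzyme Ace lower (-1.30 ± 0.28), and the list was not called.

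Camera called 13 of 26 lists at 16 weeks. The 6 higher were endothelial (median 0.37), mesangial (median 0.54), inflammatory (2 of 21 members higher, 1 lower), fatty acid oxidation, immediate early and kidney injury. The 7 lower were parietal, distal nephron, lymphocyte (median -0.09), interferon, lipid and sterol synthesis, oxidative phosphorylation (median -0.15) and insulin signalling. No call held with the correlation estimated (adjusted p = 0.351 to 0.819 with an estimated correlation). Replicate 4 of ob/ob stood apart on the endothelial and mesangial lists. Without it the endothelial mean difference was 0.20 in place of 0.44 and the call was lost (camera adjusted p = 0.23). The mesangial difference was then 0.38 in place of 0.58 and the call held (camera adjusted p = 0.0019). Calls were also lost without wild-type replicate 2 for the lymphocyte (highest adjusted p = 0.449), interferon (0.216) and parietal lists (0.184). The oxidative phosphorylation call was lost without ob/ob replicate 4 (0.0629) or wild-type replicate 3 (0.149), among others. Nphs1 differed by 0.18 (adjusted p = 0.938) and Wt1 by -0.09 (adjusted p = 0.964). The count of 542 became 271 and 243 without ob/ob replicates 3 and 4, 842, 271 and 281 without wild-type replicates 2, 3 and 4, and 65 (36 higher, 29 lower) when only the 8 arrays of that age were fitted. Cdkn1a, Aldh1a7, Clca3a1, Agt, Apob, Scd1, Insig1, Cyp51 and Col5a2 stayed past the threshold under all alternatives, while other genes named at 16 weeks lost the call under at least 1, Kap among them (adjusted p = 0.226 with only the arrays compared). Here too, genes with an absolute difference below 1 lose it by definition where at least 1 is required.

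At 24 weeks podocyte genes were lower in ob/ob glomeruli. They included the phosphatase Ptpro (-3.45 ± 0.61 log2 units, adjusted p = 0.000394, n = 4 per genotype), the semaphorin Sema3g (-3.28), podocalyxin, Podxl (-2.72 ± 0.63), Nphs1 (-2.13 ± 0.56, adjusted p = 0.00708) and Wt1 (-1.94 ± 0.45). Of 27 measured podocyte genes 21 were lower and 6 did not pass, and 25 were lower when adjusted over the list alone (median -1.60, camera adjusted p = 9.33e-10; adjusted p = 0.614 with an estimated correlation). Without the 3 arrays of low separation, none of the 5 podocyte genes above passed by limma: Ptpro differed by -1.07, Sema3g by -0.61, Podxl by -0.03, Nphs1 by -0.82 and Wt1 by -0.77 (adjusted p = 0.457 to 0.99). In that setting, which compares 1 ob/ob array with 4, the podocyte list was not called (lower, camera adjusted p = 0.0508), and with the separation as covariate it was called lower (camera adjusted p = 1.1e-06) while none of those 5 genes passed by limma (adjusted p = 0.115 to 0.366). With that covariate Ptpro differed by -2.16, Sema3g by -1.78, Podxl by -1.45, Nphs1 by -1.74 and Wt1 by -1.59, so the lost calls do not show the falls to be absent. Cdkn1c, a cell cycle inhibitor of podocytes, differed by -2.51 with all arrays (adjusted p = 0.00298) and by 0.01 without those 3.

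Genes of the glomerular endothelial list were also lower at 24 weeks, 13 of 22 over all genes and 17 over the list alone (median -1.07, camera adjusted p = 2.72e-05; adjusted p = 0.771 with an estimated correlation). The tight junction gene Cldn5 fell by 1.71, the vascular growth factor receptor Kdr by 1.98 and endomucin, Emcn, by 2.10, and without the 3 arrays they differed by -1.18, -0.51 and -0.50. The mesangial list had 1 of 17 higher and 6 lower, 1 and 9 over the list alone, with the receptor Pdgfrb at -1.57 (-0.43 without the 3 arrays). The distal nephron list had 9 of 20 lower, 10 over the list alone, with the steroid-inactivating enzyme Hsd11b2 at -3.11 ± 0.60 (-0.90 without the 3 arrays). The fibrosis list had 1 of 28 higher and 12 lower, also 1 and 12 over the list alone, oxidative phosphorylation 10 of 24 lower, 12 over the list alone, the unfolded protein response 8 of 18 lower, 8 over the list alone, and insulin signalling 3 of 20 higher and 12 lower, 3 and 12 over the list alone.

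The lipid genes kept their direction in the setting without the 3 arrays. Lipid and sterol synthesis had 15 of 18 members lower at 24 weeks, 16 over the list alone (median -0.78, camera adjusted p = 8.21e-10; adjusted p = 0.423 with an estimated correlation). Cyp51 fell by 1.95 ± 0.21 (adjusted p = 3.31e-06), Insig1 by 1.74 and the farnesyl diphosphate synthase Fdps by 1.41 ± 0.19, and without the 3 arrays they differed by -2.14, -1.94 and -1.32 (adjusted p = 0.00266, 0.0314 and 0.041). Fatty acid oxidation and PPAR targets had 7 of 21 higher and 1 lower, 7 and 1 over the list alone (median 0.37, camera adjusted p = 0.00466; adjusted p = 0.819 with an estimated correlation). Angptl4 rose by 3.22 ± 0.58 and the kinase Pdk4 by 3.15 ± 0.78, and without the 3 arrays the differences were 5.09 and 6.17. The interferon list had 13 of 18 lower, also 13 over the list alone, such as the guanylate-binding protein Gbp3 (-1.49, and -1.35 without the 3 arrays, adjusted p = 0.0477). The basement membrane list had 1 of 18 higher and 5 lower, the same numbers over the list alone, with the laminin Lama4 at -0.81 ± 0.10 and the collagen Col15a1 at -1.29 ± 0.18 (-0.62 and -1.22 without the 3 arrays).

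Clca3a1 rose by 2.85 ± 0.30 at 24 weeks (adjusted p = 1.96e-06), Agt by 2.60 ± 0.36 and Slc5a10 by 3.08 ± 0.50, and without the 3 arrays the differences were 3.22, 3.53 and 3.03, the last with adjusted p = 0.0844. Kap differed by -5.10 ± 0.88 and Slc22a19 by -3.78 ± 0.51, both past the threshold, against -5.33 (adjusted p = 0.0545) and -4.17 (adjusted p = 0.0118) without the 3 arrays. Cdkn1a rose by 2.44 ± 0.55 (4.69 without the 3 arrays). Havcr1 fell by 2.88 ± 0.39 (adjusted p = 3.74e-05), against -2.59 (adjusted p = 0.0594) without the 3 arrays. The sugar-responsive transcription factor Mlxipl rose by 2.75 ± 0.41 and the cornified envelope gene Sprr1a by 2.99 ± 0.55, and without the 3 arrays these differed by 0.85 and 1.39 (adjusted p = 0.428 and 0.224).

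In all, 6248 genes (25.9%) passed at 24 weeks, 1716 higher and 4532 lower. Leaving out the 3 arrays, 239 genes passed, 148 higher and 91 lower, of which 162 were among the 6248; that fit leaves 1 ob/ob array at this age, which is assumed to vary like the arrays of the other groups. With the separation of each array as covariate 972 genes passed, 446 higher and 526 lower, of which 649 were among the 6248. The count was 4066 without ob/ob replicate 4, 3906 without wild-type replicate 2 and 2105 when only the 8 arrays of that age were fitted, and cyclic loess scaling gave 2182 higher and 3231 lower. With all probe sets the balance turned, with 6318 higher and 5497 lower. Camera called 11 of 26 lists, fatty acid oxidation higher and 10 lower, and no call held with the correlation estimated (adjusted p = 0.423 to 0.819 with an estimated correlation). Without the 3 arrays the podocyte call (adjusted p = 0.0508) and those for the mesangial (adjusted p = 0.11), endothelial (adjusted p = 0.381), fibrosis (adjusted p = 0.685), oxidative phosphorylation (adjusted p = 0.134), unfolded protein response (adjusted p = 0.606) and insulin (adjusted p = 0.114) lists were lost, and those for lipid and sterol synthesis (lower, adjusted p = 4.67e-11), interferon response (lower, adjusted p = 0.000188), distal nephron (lower, adjusted p = 0.00167) and fatty acid oxidation (higher, adjusted p = 1.06e-11) held at the preset correlation. With 1 array left out, the mesangial (highest adjusted p = 0.122, without ob/ob replicate 4), fatty acid oxidation (0.179, without ob/ob replicate 3) and unfolded protein response calls (0.114, without ob/ob replicate 1) were lost.

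**Figure D4:**
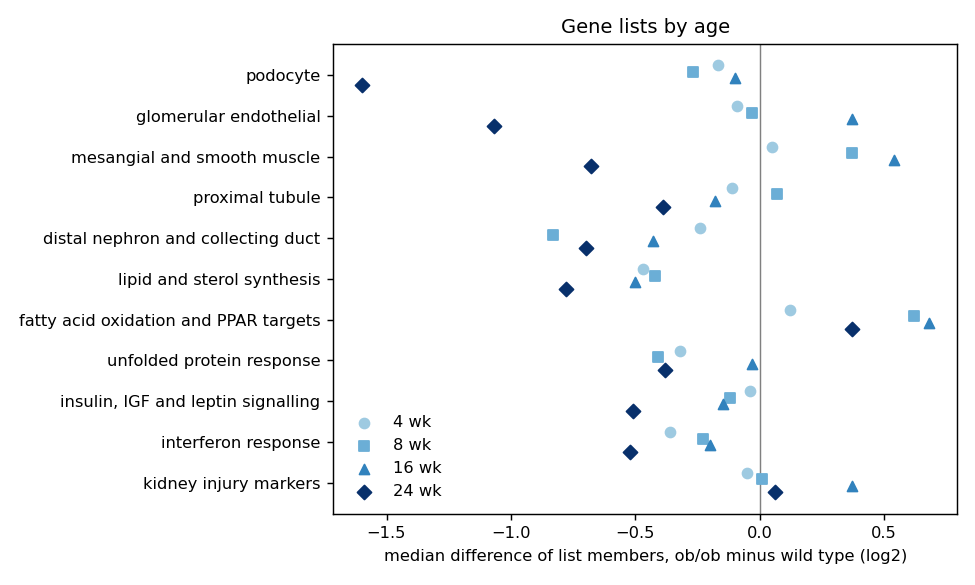
Median difference of list members, ob/ob minus wild type in log2 units (x axis), for 11 gene lists at 4 ages, each age with its own symbol. The podocyte list has medians of -0.17, -0.27, -0.10 and -1.60 at 4, 8, 16 and 24 weeks, the last with 3 arrays of low control separation, and lipid and sterol synthesis has -0.47, -0.42, -0.50 and -0.78.

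Several genes differed between genotypes in the same direction at 8, 16 and 24 weeks. Kap, Slc22a19, Scd1, Casr and Umod were lower, and Slc5a10, Clca3a1, Agt and Apob higher, at 8, 16 and 24 weeks. In all, 31 genes were higher and 70 lower at these 3 ages, and no gene passed at all 4 ages. At 8 and 16 weeks 48 genes were higher at both ages, where 1.41 would be expected of independent lists, and 88 lower, where 3.38 would be expected (one-sided Fisher exact p = 5.32e-61 and 2.84e-102), with no gene opposite. At 16 and 24 weeks 111 were higher (15.67 expected) and 249 lower (60.55 expected), with 3 opposite, and at 8 and 24 weeks 49 (10.97 expected) and 143 (47.58 expected), with 5 opposite. Each age used its own animals, so no controls were shared. The ages did share 1 variance estimate per gene in the fit, and genes are correlated. The lists are therefore not independent, and the expected counts and Fisher p values are only a rough guide. Of the 407 genes past the threshold at 8 weeks, 93.9% had the same sign at 4 weeks, where Slc22a19 differed by -2.88 ± 0.59, Clca3a1 by 1.66 ± 0.35 and Kap by -2.05 ± 1.02, none past the threshold. Across genes, which are not independent replicates, the correlation of the differences was 0.52 between 8 and 16 weeks, 0.42 between 16 and 24 weeks and 0.36 to 0.39 between 4 weeks and each later age. With the 3 arrays left out, 40 genes were shared at 8, 16 and 24 weeks, 23 higher and 17 lower, and with the separation as covariate 116, 76 higher and 40 lower, so the balance of direction turned in both settings.

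The ob allele is a mutation of Lep, the leptin gene, so Lep and its receptor were read at each age. Lep differed by -0.07, -0.03 and 0.20 at 4, 8 and 16 weeks, none past the threshold, and by 0.44 ± 0.15 at 24 weeks (adjusted p = 0.0275), or 0.25 without the 3 arrays (adjusted p = 0.707). A probe set outside the mutated base does not check the genotype. Lepr, the leptin receptor, differed by -0.08, -0.54, -0.50 and -0.80 ± 0.18 at 4, 8, 16 and 24 weeks, and only the last passed (adjusted p = 0.00283; -0.48 with adjusted p = 0.511 without the 3 arrays). Of 303 tested genes within 20 Mb of Lep, 1 changed in the same direction at 3 or more ages. Of the 23565 other genes with a position 100 did so (Fisher exact p = 1, two-sided). The 1 gene was Tspan33, a tetraspanin gene named here after its values were seen, which lies 0.6 Mb from Lep. It differed by 1.22 ± 0.22, 1.33, 1.12 and 0.66 at 4, 8, 16 and 24 weeks, the first not past the threshold (adjusted p = 0.143). The Fisher test compares counts of genes and does not tell why this gene differed.

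Whether the genotype difference changed with age was tested as an interaction. Lgr5, a Wnt-linked receptor, had differences of 0.01, -0.26, -0.50 and -0.72 at 4, 8, 16 and 24 weeks, and was the only gene whose difference at 24 weeks departed from that at 4 weeks (-0.73 ± 0.12, adjusted p = 0.0265). Over all 4 ages 18 genes passed limma's F test. Akr1c20, an aldo-keto reductase, had differences of -0.52, -0.12, -1.94 and -2.62 (adjusted p = 0.0108), the transaminase Gpt2 of -0.51, 0.04, -0.94 and -1.76 (adjusted p = 0.026) and the cholesterol transfer gene Gramd1b of 0.22, 0.33, 0.90 and 2.15 (adjusted p = 0.0357). Txndc5, a protein disulfide isomerase, had -0.24, -0.13, -0.47 and -1.08 (adjusted p = 0.0344), and Gatm, the first enzyme of creatine synthesis, -0.16, 0.07, -0.78 and -1.35 (adjusted p = 0.0428). At unadjusted p under 0.05 there were 3757 genes for 24 against 4 weeks and 4095 over all ages. Camera called 10 of 26 lists for 24 against 4 weeks, cell cycle and fatty acid oxidation higher and podocyte, endothelial, mesangial, distal nephron, fibrosis, lipid and sterol synthesis, oxidative phosphorylation and insulin signalling lower, none with the correlation estimated (adjusted p = 0.614 to 0.86 with an estimated correlation). The podocyte call was lost without the 3 arrays of low separation (adjusted p = 0.874). The podocyte, endothelial and oxidative phosphorylation calls held whichever array was left out. Those for cell cycle (highest adjusted p = 0.571), fibrosis (0.394), distal nephron (0.339), lipid and sterol synthesis (0.248), insulin (0.136) and mesangial (0.0773) lists were lost without wild-type 4 week replicate 1. The fatty acid oxidation call was lost without ob/ob 24 week replicate 3 (0.397).

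Without ob/ob 24 week replicate 3, the array of that group with high separation, 2713 genes passed for 24 against 4 weeks and 3489 over all ages. For 24 against 4 weeks the count was 77, 65, 11 and 2 without wild-type 24 week replicate 1, wild-type 24 week replicate 4, wild-type 4 week replicate 1 and ob/ob 4 week replicate 1, and limma called 0 genes without ob/ob 24 week replicates 1, 2 or 4, wild-type 24 week replicate 3, ob/ob 4 week replicates 2 or 3, or wild-type 4 week replicates 2 or 3. Without the 3 arrays of low separation, 4 genes passed for 24 against 4 weeks and 3 over all ages, none of them among the genes called with all arrays, and the Lgr5 difference was -0.57 (adjusted p = 0.35). In that setting the F test calls were lost for Akr1c20 (adjusted p = 0.0553), Gatm (0.0553), Gpt2 (0.143), Lgr5 (0.243), Txndc5 (0.55) and Gramd1b (0.753). With the separation as covariate Akr1c20 kept its call (adjusted p = 0.0427) and the other 5 lost it (adjusted p = 0.107 to 0.306). Cyclic loess scaling gave 35 higher and 6 lower for 24 against 4 weeks.

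The 18 genes of the F test over all ages likewise depended on which arrays were used. At 24 weeks the count was 2, 4 and 1 without ob/ob replicates 1, 2 and 4, and 1, 1 and 158 without wild-type replicates 2, 3 and 4. At 16 weeks it was 29 and 3 without ob/ob replicates 1 and 3, and 172 and 10 without wild-type replicates 2 and 4. At 8 weeks it was 4 and 4 without ob/ob replicates 1 and 2, and 1, 7, 11 and 1 without wild-type replicates 1, 2, 3 and 4. At 4 weeks it was 2 and 4 without ob/ob replicates 2 and 3, and 2 without wild-type replicate 2.

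Ageing was read within each genotype as 24 against 4 weeks. In wild type, proliferation genes fell: Mki67 (-2.51 ± 0.33 log2 units, adjusted p = 0.000109, n = 4 at 24 weeks and 3 at 4 weeks), the cyclin Ccna2 (-1.18), the mitotic motor Kif11 (-1.16) and the topoisomerase Top2a (-1.15). Of 27 measured cell cycle genes 17 fell and 10 did not pass, and 22 fell when adjusted over the list alone (median -0.57, camera adjusted p = 8.39e-46; adjusted p = 0.0107 with an estimated correlation, the only list call of all comparisons that held). Apob rose by 4.09 ± 0.44, the cytochrome Cyp2a4 by 3.75, the retinaldehyde dehydrogenase Aldh1a1 by 3.10, the calcification inhibitor Mgp by 2.79, the immunoglobulin heavy chain segment Ighv1-53 by 2.93 and Havcr1 by 2.27 ± 0.43 (adjusted p = 0.00467). The macrophage and myeloid list had 3 of 25 higher, 4 over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.614 with an estimated correlation), and its 3 members were the antigen presentation genes H2-Ab1 (1.74), H2-Eb1 (1.43) and H2-Aa (0.96). Basement membrane genes had 2 of 18 lower, 1 higher and 4 lower over the list alone: the collagen Col4a5 (-0.52) and the nidogen Nid2 (-0.70). The steroid synthesis genes Cyp11b1 (-1.89 ± 0.47), Star (-1.46), Cyp21a1 (-1.46) and Cyp11a1 (-1.34), which the adrenal cortex expresses strongly, were lower, and the prostaglandin synthase Ptgds fell by 1.36.

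In all, 269 genes changed with age in wild type, 167 higher and 102 lower. Camera called 11 lists: podocyte, endothelial, macrophage, complement (median 0.24), inflammatory, interferon, kidney injury and insulin signalling higher, and basement membrane, oxidative phosphorylation and cell cycle lower, of which 10 were lost with the correlation estimated (adjusted p = 0.5 to 0.819 with an estimated correlation). At the preset correlation the insulin (highest adjusted p = 0.333), complement (0.285) and endothelial calls (0.0586) were lost without wild-type 4 week replicate 1. The basement membrane call was lost without replicate 2 (0.116) and the interferon call without replicate 3 of that group (0.0835). The count was 133 and 149 without wild-type 4 week replicates 2 and 3, and without either of them Star, Cyp21a1, Cyp11a1 and Cyp11b1 did not pass. Cyclic loess scaling turned 167 higher and 102 lower into 151 and 149.

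In ob/ob the same 24 against 4 week comparison gave falls in the cell cycle genes, with Mki67 at -2.14 ± 0.33 (adjusted p = 0.00036, n = 4 at 24 weeks and 3 at 4 weeks), Top2a at -1.04, Kif11 at -0.99 and Ccna2 at -0.97. Of 27 members 19 fell and 8 did not pass, 23 over the list alone (median -0.44, camera adjusted p = 1e-16; adjusted p = 0.351 with an estimated correlation). With the 3 arrays of low separation left out, Mki67 differed by -2.05 (adjusted p = 0.0778), and camera kept the list lower (adjusted p = 3.27e-11). Cyp24a1 rose by 5.50 ± 0.89, Aldh1a1 by 4.60 and Apob by 4.57 (6.65, 5.10 and 5.92 without the 3 arrays), while the amino acid transporter Slc7a12 rose by 3.26, or 0.74 without the 3 arrays. The brush border peptidase Xpnpep2 fell by 2.29 ± 0.26 and the vesicular monoamine transporter Slc18a1 by 2.24 ± 0.36 (-2.14 and -2.59 without the 3 arrays). Oxidative phosphorylation had 17 of 24 lower, 20 over the list alone (median -0.57, camera adjusted p = 5.3e-11; adjusted p = 0.53 with an estimated correlation). The macrophage list had 5 of 25 higher, 8 over the list alone (camera adjusted p = 1e-07; adjusted p = 0.5 with an estimated correlation), with the growth factor receptor Csf1r at 0.85 and the complement gene C1qb at 1.30, against 0.56 and 0.80 without the 3 arrays, where neither passed. Without ob/ob 24 week replicate 2, which stood apart on this list (7.54, others 6.35 to 6.55), the list mean rose by 0.31 in place of 0.57 (camera adjusted p = 1.24e-05). The basement membrane list had 4 of 18 lower, 5 over the list alone, and the fibrosis list 4 of 28 lower, 8 over the list alone, neither called by camera (adjusted p = 0.0873 and 0.13), among them Lamc1 (-1.10), Nid1 (-1.33) and Col3a1 (-0.65), none of which passed without the 3 arrays. Sparc, a matrix protein gene, differed by -1.51 with all arrays (adjusted p = 0.0192) and by 0.15 without the 3.

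In all, 2669 genes changed with age in ob/ob, 825 higher and 1844 lower, against 136 without the 3 arrays (95 higher, 41 lower, 67 of them among the 2669) and 592 with the separation as covariate. The count was 1481, 1190, 5745 and 1319 without ob/ob 24 week replicates 1, 2, 3 and 4, 817 and 697 without ob/ob 4 week replicates 2 and 3, and 236 with only the arrays compared, and cyclic loess scaling gave 1061 higher and 1072 lower, and all probe sets 2002 and 1953. Camera called 9 lists, macrophage, adipocyte (3 of 10 members higher, 5 over the list alone), inflammatory and kidney injury higher, and podocyte, mesangial, lipid and sterol synthesis, oxidative phosphorylation and cell cycle lower, none with the correlation estimated (adjusted p = 0.351 to 0.855 with an estimated correlation). The podocyte and mesangial lists turned from lower to higher without the 3 arrays (adjusted p = 0.00106 and 0.0391). Both calls were already lost without ob/ob 24 week replicate 2 (adjusted p = 0.109 and 0.0687) or replicate 4 (adjusted p = 0.137 and 0.183). The inflammatory and kidney injury calls were lost without replicate 3 (adjusted p = 0.108 and 0.0858). An age change past the threshold in 1 genotype and not in the other is not shown to differ between them; the interaction test above gives the difference.

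Lists with no camera call in any of the 7 comparisons were proximal tubule (smallest adjusted p = 0.0808), oxidative stress and NRF2 targets (0.101), glycolysis and hypoxia response (0.145), renin-angiotensin and vasoactive (0.0916) and circadian clock (0.149). Over all lists and comparisons 73 of 182 tests were called, and 1 with the correlation estimated.

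**Figure D5:**
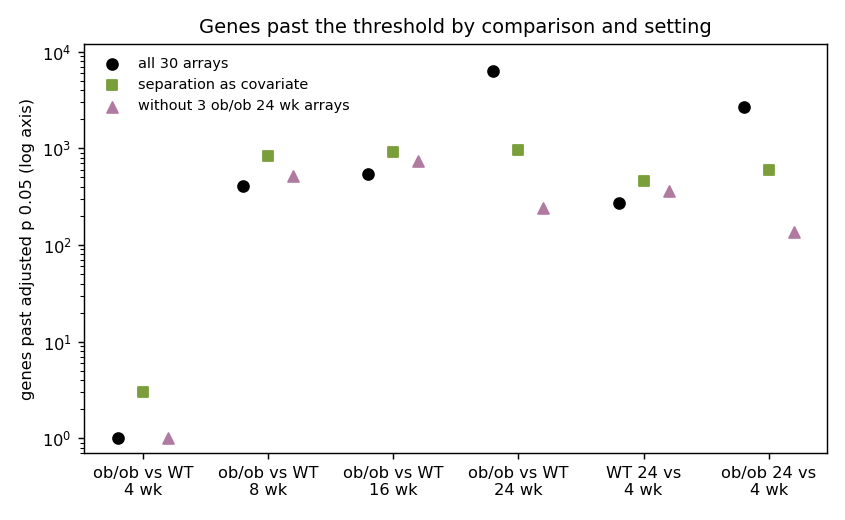
Genes past adjusted p 0.05 (y axis, log scale) in 6 comparisons with all 30 arrays, with the exon-intron separation of each array as covariate, and without the 3 ob/ob 24 week arrays of lowest separation. At 24 weeks the genotype comparison gives 6248, 972 and 239 genes in these settings.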

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

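The settings without the 3 arrays of low separation and with the separation as covariate were chosen after the result was seen. So were the podocyte against endothelial test, both Kap tests, the cortex and medulla split of adrenal markers and the sex-biased gene test. The podocyte test of array quality, the pooled adrenal test and the regroupings of arrays were written down before their own outcome was known.

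In 5 of 102 groups tested, 1 array stood apart by Dixon's ratio for groups of 4 arrays, where chance gives about 1 in 20. They were the distal nephron mean of ob/ob 8 week replicate 1 (11.84, others 11.50 to 11.53, ratio 0.901), the endothelial mean of ob/ob 16 week replicate 4 (12.11, others 11.10 to 11.20, ratio 0.899) and its mesangial mean (10.67, others 9.79 to 9.90, ratio 0.877). The others were the parietal mean of wild-type 24 week replicate 3 (9.55, others 9.21 to 9.25, ratio 0.894) and the macrophage mean of ob/ob 24 week replicate 2 (7.54, others 6.35 to 6.55, ratio 0.831). With all arrays, limma called a change of the genotype difference with age for Lgr5 from 4 to 24 weeks (adjusted p = 0.0265) and over 4 ages for Akr1c20 (0.0108), Gpt2 (0.026), Lgr5 (0.0344), Txndc5 (0.0344), Gramd1b (0.0357) and Gatm (0.0428); without the 3 arrays of low separation each call was lost (smallest adjusted p = 0.0553). Probe sets with no or several symbols passed in 57 cases at 8 weeks, 129 at 16 weeks and 5772 at 24 weeks, of 24190 tested; they are not named here.

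The lower podocyte list at 24 weeks (-1.58 in list mean) may come from array or RNA quality, since the 3 ob/ob arrays with the lowest list values are those of low separation. The slope of the podocyte mean on separation, fitted within groups over 26 other arrays, predicted a shift of 0.22 (95% interval -0.54 to 0.97). That interval lies above the observed difference, which had been set down as speaking against quality, but those 26 arrays reach down only to 0.826 while the 3 arrays lie at 0.762 to 0.783, so the slope is not known where it is needed and quality and genotype cannot be told apart. A smaller share of glomeruli stays open: the podocyte minus endothelial mean was lower in ob/ob (-0.47, no overlap, exact permutation p = 0.0286, n = 4 per genotype), but at 16 weeks it was as low (-0.55, no overlap) while the podocyte mean differed by only -0.11, so this gap is not particular to the 24 week fall. A loss of podocyte transcripts with genotype also remains open: ob/ob replicate 3, with a separation of 0.861, had a podocyte mean of 11.09 against 11.32 to 11.52 in wild type.

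Lower Kap and Slc22a19 at 8, 16 and 24 weeks could reflect a smaller share of proximal tubule in ob/ob samples. The other 23 proximal tubule genes do not show it: their median difference was 0.07 at 8 weeks and -0.16 at 16 weeks, and their lower quartile was no lower than -0.52, against -4.60 and -4.05 for Kap. At 24 weeks their median was -0.36, their lower quartile -0.57 and the lowest member -1.41 (Ttc36), against -5.10 for Kap. With the separation as covariate 6 of 6 differences of Kap and Slc22a19 stayed past the threshold. At 8 and 16 weeks the separation itself differed by only 0.000 and -0.008, so array quality is not a likely cause there. At 24 weeks the covariate cannot decide, as the 3 arrays of low separation lie below the range of the others. In ob/ob 24 week replicate 3, of high separation, Kap was 12.43, against 16.54 to 18.94 in wild type.

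The fall of 4 steroid synthesis genes with age in wild type could come from adrenal tissue carried over with some kidneys. Within groups, over 15 wild-type arrays, the mean of these genes went with the mean of 10 other adrenal markers at Pearson r = 0.47 (permutation p = 0.0908) and Spearman rho = 0.40 (permutation p = 0.137). Without wild-type 4 week replicate 3 and wild-type 8 week replicate 2, farthest from the median, r was 0.17. Taken apart after that was seen, 6 cortex markers went with these genes at r = 0.78 (permutation p = 0.00081; 0.71 without the same arrays) and 4 medulla markers at r = -0.42 (permutation p = 0.163), which carried-over cortex would give, as would joint control of steroid genes in kidney cells, and the pooled r lay between the bounds of 0.3 and 0.5 set beforehand, so the cause stays open. Among those markers Hsd3b1 of the cortex differed by -0.90 ± 0.24 (adjusted p = 0.0772), and the medulla genes Dbh, Pnmt, Chga and Ddc by 0.03, 0.02, 0.03 and 0.18. The mean of the 4 steroid synthesis genes was 5.73, 6.69 and 7.88 in wild-type 4 week replicates 1, 2 and 3. It was 6.54 in wild-type 8 week replicate 2 and 6.23 in wild-type 24 week replicate 4. In the other wild-type arrays it was 4.82 to 5.31, and in the ob/ob arrays 4.84 to 5.37. In ob/ob Cyp11a1, Cyp11b1, Cyp21a1 and Star changed with age by -0.04, -0.06, 0.12 and 0.07.

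Arrays were also regrouped in every possible way within a comparison, or in 100 reassignments of genotype within age for the interaction, with the real grouping counted. At 8 weeks 1 of 35 splits, the real one, gave at least 407 genes (highest other 1). At 16 weeks 1 of 35 gave at least 542 (highest other 451), and for age in wild type 1 of 35 gave at least 269 (highest other 152). No other split reached these 3 counts, which is the most that 35 splits can show. Chance is thus less likely for them but not excluded, and no adjustment was made over the comparisons. At 24 weeks 2 of 35 splits gave at least 6248 genes (highest other 6684), and for age in ob/ob 3 of 35 gave at least 2669 (highest other 6368), so chance is not excluded, and each of those higher splits keeps the 3 arrays of low separation together. For the interaction, 10 of 100 reassignments gave at least 1 gene for 24 against 4 weeks (highest other 3140). Over all ages 6 of 100 gave at least 18 (highest other 1869). Chance is not excluded. A reassignment that turns genotype round at 1 age makes a difference shared by the ages look like an interaction, so these draws cannot decide the question. Why some of them gave such high counts was not tested. At 4 weeks 2 of 10 splits gave at least 1 gene (highest other 3), and 10 splits are too few to exclude chance.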

How the results depend on the processing

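Of 157 named gene results past the threshold, 46 stayed past it in all alternatives and 2 reversed. The alternative of an absolute difference of at least 1 removes smaller differences by definition. There 26 of 166 named gene results lost the call, so the count of 46 depends in part on effect size. Why the counts moved was not tested beyond the settings given. Those without the 3 arrays and with the separation as covariate were added after the data had been seen. Array quality weights do not correct for low separation. They gave ob/ob 24 week replicate 3, the array of that group with high separation, a weight of 0.217. Replicates 1, 2 and 4, of low separation, had 0.674, 1.172 and 0.699. Weighted counts that use this group therefore lean on the 3 arrays of low separation. The proximal tubule list mean rose with the separation within groups, so the tubule covariate does not adjust for tubule share alone.

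At 4 weeks (1 gene) limma called 0 with only the arrays compared (1082 at unadjusted p under 0.05 with all arrays), 2 with cyclic loess, 31 with array weights, 2 with all probe sets, 2 with the tubule covariate, 3 with the separation covariate, and 0 (without ob/ob replicate 3) to 6 (without wild-type replicate 1) with 1 array left out. At 8 weeks (407) it called 625 with cyclic loess (326 higher, 299 lower), 1697 with weights, 129 at an absolute difference of at least 1, 999 with the tubule covariate (579 higher, 420 lower), 825 with the separation covariate, and 166 (without ob/ob replicate 4) to 324 (without wild-type replicate 3). At 16 weeks (542) it called 65 with only the arrays compared, 3025 with weights, 204 at a difference of at least 1, 927 with the separation covariate, and 243 (without ob/ob replicate 4) to 842 (without wild-type replicate 2).

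At 24 weeks (6248) limma called 2105 with only the arrays compared, 11815 with all probe sets (6318 higher, 5497 lower), 1032 at a difference of at least 1, 3924 with the tubule covariate, 239 without the 3 arrays, 972 with the separation covariate, and 3906 (without wild-type replicate 2) to 8514 (without ob/ob replicate 3). For 24 against 4 weeks between genotypes (1) it called 41 with cyclic loess (35 higher, 6 lower), 4001 with weights, 0 with all probe sets, 0 at a difference of at least 1 (3757 at unadjusted p under 0.05 with all arrays), 4 without the 3 arrays, and 0 (without ob/ob 24 week replicate 1, among others) to 2713 (without ob/ob 24 week replicate 3). Over all ages (18) the F test gave 68 with cyclic loess, 5387 with weights, 11 with trend and robust settings, 1 with all probe sets, 77 with the tubule covariate, 3 without the 3 arrays, 6 with the separation covariate, and 1 (without ob/ob 24 week replicate 4, among others) to 3489 (without ob/ob 24 week replicate 3).

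For age in wild type (269) limma called 160 with only the arrays compared, 541 with weights, 102 at a difference of at least 1, 456 with the separation covariate (228 higher, 228 lower), and 133 (without 4 week replicate 2) to 314 (without 24 week replicate 4). For age in ob/ob (2669) it called 236 with only the arrays compared, 7159 with weights, 392 at a difference of at least 1, 1680 with the tubule covariate, 136 without the 3 arrays, 592 with the separation covariate, and 697 (without 4 week replicate 3) to 5745 (without 24 week replicate 3).

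With replicate number as block the counts were 0 at 4 weeks, 266 at 8 weeks, 353 at 16 weeks, 1502 for age in ob/ob, and 0 for both interaction tests, so Akr1c18 was lost at 4 weeks. Arrays of the same number and age were not paired: of 15 such pairs 6 had a correlation above 0.1, with a range of -0.35 to 0.58.

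Of 73 list calls 1 held with an estimated correlation, and fry's directional test called 21. Of 610 list results with 1 array left out, 520 kept the call, 90 lost it and none reversed. The count of genes shared by 8, 16 and 24 weeks was 101, against 40 from the top 500 genes, 40 without the 3 arrays (23 higher, 17 lower) and 116 with the separation covariate (76 higher, 40 lower). Without the 3 arrays Cdkn1c at 24 weeks went from -2.51 to 0.01, Sparc with age in ob/ob from -1.51 to 0.15, and the podocyte and mesangial lists with age in ob/ob from lower to higher (adjusted p = 0.00106 and 0.0391).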

Other observations

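The podocyte balance and the sex-biased lists were chosen after the data had been seen, and their lists of sex-biased genes were written from general knowledge. Their 24 week values include the 3 arrays of low separation.

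In wild type the immunoglobulin light chain segment Igkv4-54 rose with age by 2.44 ± 0.35 log2 units (adjusted p = 0.00027, n = 4 at 24 weeks and 3 at 4 weeks), and the growth factor binding protein Igfbp3 by 1.74 (adjusted p = 0.00122). Of 237 genes annotated as V segments, a class counted after the data had been seen, 32 rose with age in wild type and 205 did not pass, and 61 rose in ob/ob and 176 did not pass. Genes past the threshold at 24 weeks were counted by transcript class, also after the data had been seen, and no test between classes was made. With genes of identical values counted once, limma called 18 of 23 ribosomal RNA genes lower, 12 of 719 small nuclear RNA genes higher and 137 lower, and 108 of 3424 pseudogenes higher and 761 lower. Of 1972 long noncoding RNA genes 305 were higher and 36 lower, of 406 microRNA genes 102 were higher and 4 lower, and of 15691 protein-coding genes 1072 were higher and 3298 lower. Among probe sets with no or several symbols 4702 were higher and 1070 lower. These counts include the 3 ob/ob arrays of low separation. Without them 128 protein-coding genes were higher and 74 lower, 6 long noncoding RNA genes higher and 2 lower, 6 pseudogenes higher and 12 lower, and no ribosomal, small nuclear or microRNA gene passed. With 1 ob/ob array left, calls are lost through lower precision alone. The 3 arrays had intron control medians of 6.79, 6.68 and 6.73, against at most 6.35 in the other arrays. Their exon control medians were 10.15, 10.18 and 9.93, against at least 10.39 in the others. This shift goes the same way as the long noncoding and microRNA rises and the protein-coding falls. Whether the pattern by class comes from those arrays was not tested and is open.

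Podocyte genes may be low relative to mesangial genes in ob/ob from 8 weeks on. The podocyte minus mesangial list mean was 1.02 ± 0.20 against 1.77 ± 0.18 at 8 weeks, 1.17 ± 0.23 against 1.86 ± 0.23 at 16 weeks and 1.20 ± 0.35 against 2.01 ± 0.23 at 24 weeks (ob/ob against wild type, SD, n = 4 each, exact permutation p = 0.0286 and 0.0458 after Benjamini-Hochberg adjustment over 8 tests). At 4 weeks the difference was -0.23 (exact permutation p = 0.1, the smallest possible with 3 against 3). Against the endothelial list the differences were -0.32 at 8 weeks (exact permutation p = 0.0571) and -0.55 and -0.47 at 16 and 24 weeks (exact permutation p = 0.0286 for each). At 8 and 16 weeks the separation differed by 0.000 and -0.008, so quality is an unlikely cause there, while a gain of mesangial transcript remains a candidate as much as a loss from podocytes: the mesangial mean was higher by 0.45 at 8 weeks (exact permutation p = 0.0857). Cell counts would be needed to separate these, and were not used here.

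A candidate reading of the fall of Slc22a7 (-1.68, -2.00 and -2.17 at 8, 16 and 24 weeks) and the early fall of Slc7a12 is that ob/ob females may lose part of the female pattern of the proximal tubule. A mean of 5 female-biased genes minus a mean of 8 male-biased genes differed by -1.45 at 8 weeks and -1.72 at 16 weeks without overlap (exact permutation p = 0.0286 for each and 0.0572 after adjustment, n = 4 per genotype). At 24 weeks it differed by -0.87 with overlap (exact permutation p = 0.0857). At 4 weeks it already differed by -1.56 without overlap (exact permutation p = 0.1, n = 3 per genotype). A rule written after the result was seen asked for no overlap at 8, 16 and 24 weeks, and 2 of 3 ages met it. The lists hold the genes that prompted the idea, so these values do not test it. Without the members already seen, 1 female-biased and 7 male-biased genes remained. The difference was then -0.75 at 8 weeks and -1.57 at 16 weeks (no overlap, exact permutation p = 0.0286 for each) and -0.42 at 24 weeks with overlap (exact permutation p = 0.4). At 4 weeks the difference was -0.49 without overlap (exact permutation p = 0.1, n = 3 per genotype). With 1 female-biased gene left the idea stays open. Cyp4a14, on the female-biased list, went the other way (2.17 at 16 weeks and 2.45 at 24 weeks). Kap is induced by androgen and fell, which this reading does not account for. Hormone levels were not used here.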
